A study of Mus musculus with 75 samples.

How the data were processed

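RNA was measured in 75 libraries of ES-E14TG2a mouse embryonic stem cells. In 58 of them 1 of 29 SNF2-type ATPases was targeted with esiRNA for 48 hours, in biological duplicate, and 17 received esiRNA against GFP. Per the labels' protocols, cells were exposed to 4-thiouridine, a nucleoside that marks newly made RNA, for 5 minutes before harvest. The libraries used here were made from total RNA after removal of rRNA with a strand-specific kit, and libraries of the labelled RNA were not used here. The series title gives the aim as the impact of nucleosome remodelers on transcription. Groups and replicate numbers were taken from the sample titles.

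Per the submitters' processing notes, the tools named were cutadapt, Trimmomatic, STAR, SAMtools, featureCounts, DESeq2 and deepTools, with versions not given, and the genome build was mm10. Their order, settings and the strand setting used in counting are not given in the sources used here. The authors deposited whole-number counts per gene with no normalization, for 55433 genes, of which 13425 had no count in any library. The batch-corrected values that the authors deposited, made with ComBat-seq per the file names, are adjusted rather than raw and were treated as scores. They come with a table that gives the batch of each library. What a batch stands for is not stated. All columns belonged to these 75 samples. The uncorrected counts were the basis of every result, and the corrected counts served as an alternative. As whole numbers they entered the same kind of count fit, but without a batch term.

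Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr by group, with a minimum count of 10 and a minimum total of 15, which left 21506. Library sizes were scaled by TMM. All 75 libraries entered 1 quasi-likelihood fit with terms for group and batch, which had 42 design columns, 33 residual degrees of freedom, a prior of 7.72 degrees of freedom and a common dispersion of 0.0396. Fitting all groups together lets groups of 2 share 1 estimate of the spread. Each knockdown was compared with the controls, p was adjusted by the Benjamini-Hochberg method within a knockdown, and a gene was called at an adjusted p under 0.05. All tests are two-sided. Standard errors of log2 fold changes come from the F statistic of that test. CPM are counts scaled to a common library total after TMM, and log2 CPM used a prior count of 0.5. Deviations of single libraries from the control mean carry no batch term. Totals per library ranged from 26 to 65.5 M with a median of 35.8 M, and the genes detected per library are counted before filtering.

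Target genes were adjusted over the 29 targets and over all genes. For the 28 other targeted genes in each knockdown the adjustment was over all genes tested. Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 36 lists in 29 knockdowns, 1044 tests. Camera with an estimated correlation and fry were run as alternatives, and members were counted both over all genes and adjusted over the list alone. The lists were 2-cell-like genes, BMP targets, cholesterol synthesis, core pluripotency, cytosolic ribosomal proteins, DNA replication, FGF and ERK feedback, fibroblast and matrix genes, formative and primed pluripotency, germline genes, glycolysis and hypoxia, heat shock, homologous recombination, Hox genes, immediate early genes, imprinted genes, subunits of INO80, SRCAP and TIP60, the integrated stress response, the interferon response, lysosome, mesendoderm, mitochondrially encoded genes, mitosis, naive pluripotency, neuroectoderm, Nodal and TGF-beta targets, the nuclear respiratory chain, NuRD subunits, p53 targets, primitive endoderm, replication-dependent histones, ribosome biogenesis, SWI/SNF subunits, trophectoderm, the unfolded protein response and Wnt targets.

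Relatives were defined by families of the ATPase domain, 9 of which had at least 2 members and gave 22 pairs. Each pair was contrasted directly in the same fit. Similarity was the mean Pearson correlation of log2 fold changes over the 22 pairs minus that over all other pairs, with 1e+05 permutations of the family labels. Because all knockdowns share controls, 12 sets of unchanged knockdowns were simulated from the control counts. The controls were also split in 12 random ways so that the knockdowns of a pair were set against different ones. The split was made within 1 fit of all libraries, so the batch terms were still shared. Recurrence was the number of knockdowns in which a gene was called in 1 direction. Pairs of controls were set against the other controls in 60 draws, fewer than the 100 planned.

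The groups, tests, gene lists, families, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the target of each knockdown. For the 5 knockdowns with the most genes called it took the 10 highest and the 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a fitted average log2 CPM of at least 3 and both replicates on the same side of the control mean, and for the others 2 and 2. Targets and placeholder symbols were left out of that part. It added up to 4 members with the smallest adjusted p from each called list, the 10 genes called in most knockdowns, and the 10 remodeler genes with the smallest adjusted p outside their own knockdown. Some genes that the rule takes are not reported here.

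Each result was also computed with no batch term, the corrected counts, RLE factors and 2 other filters. Targets and counts of called genes were also computed with DESeq2 1.42.0, a fit of the knockdown and controls alone (possible for 24 knockdowns), the replicate number as a block and each replicate left out, and the counts with a 2-fold minimum. These were fixed in advance. Chosen after the data were seen were the block for the other results, the antisense share as a covariate, a GC trend per library as an offset, the fit without batches 1, 2 and 4, each control left out, and the fit without 3 libraries of doubtful label. The antisense share is the log2 of counts on genes annotated as antisense over counts on protein-coding genes, per library. When 1 replicate is left out, the other is assumed to vary like the other groups.

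Gene positions and types came from an mm10 annotation (release 21), which held 53569 of the gene symbols and gave coordinates for 21156 of the genes tested. The steps were tested on simulated counts with 200 genes changed per knockdown, with seed 7. No 2 libraries agreed within sampling noise: over genes with a mean count of at least 50, the lowest chi-square per degree of freedom among 2775 pairs was 9.55, and 18 within a group. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes with near-identical copies, and antisense genes, are given as uncertain.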

Results

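RNA was measured in ES-E14TG2a (E14) cells, a male mouse embryonic stem cell line, 48 hours after transfection with esiRNA, a pool of short RNAs made by enzymatic digestion of a long double-stranded RNA matching 1 transcript. Each of 29 genes was targeted in 2 biological duplicates. All 29 encode ATPases of the SNF2 type, a type that includes the motor subunits of complexes that move, evict or edit nucleosomes. The reference group held 17 libraries of cells given esiRNA against GFP, which has no counterpart in the mouse genome. The libraries were built from rRNA-depleted total RNA with a strand-specific protocol. Counts assigned to genes summed to between 26 and 65.5 M (M for mega) per library, with a median of 35.8 M. The long noncoding RNA Gm26917, which overlaps ribosomal DNA repeats, took between 13.1% and 52.3% of them. The libraries carried 13 batch numbers, and 5 of these batches held no control library. Both libraries of Chd9, Ercc6, Ercc6l, Rad54l and Ttf2 lay in such batches. These knockdowns were tied to the controls only through other knockdowns. Counts on antisense genes were raised in some libraries of batches 1, 2 and 4, where their log2 ratio to protein-coding counts reached -8.23, -7.87 and -8.21, against at most -9.19 in any other batch. Fold changes below are log2 values against the 17 controls with the batch in the model, given with their standard error, for 2 libraries of each knockdown. Positions are those of mm10.

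**Figure D1:**
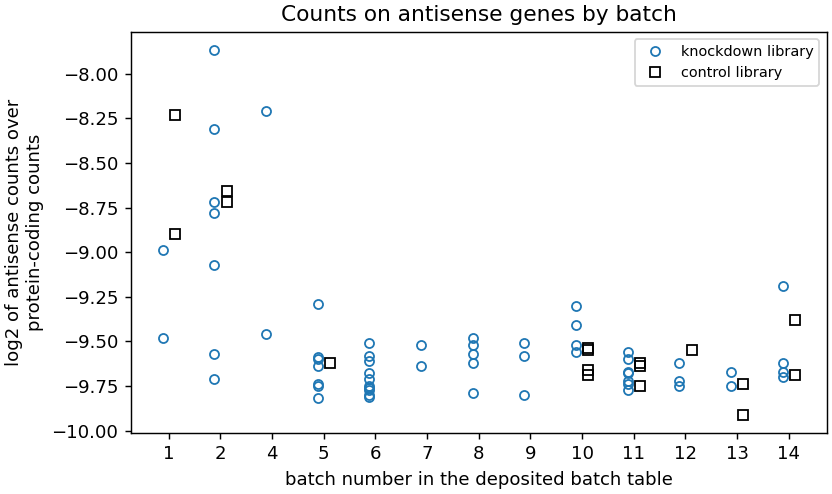
Counts on annotated antisense genes, as the log2 of their ratio to protein-coding counts (vertical axis), in each library by batch number (horizontal axis), with controls and knockdowns marked. Libraries above -9.19 occur in batches 1, 2 and 4 alone, and in those batches other libraries lie at the level of the rest.

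The first comparison asked whether each labelled knockdown lowered its target. All 29 targeted RNAs were lower than in the controls when p was adjusted over the 29 targets, and 18 were also lower when it was adjusted over all 21506 genes tested. Depletion was deepest for Smarca5, the ATPase of the ISWI complexes (ENSMUSG00000031715.14, chromosome 8, 80698507 to 80739497), at -3.94 ± 0.33 or 6.51% of control. Its 2 libraries held 5.50 and 5.24 CPM against 83.2 ± 27.1 CPM (SD, n = 17). Smarca4, which encodes BRG1 of the SWI/SNF complexes (ENSMUSG00000032187.16, chromosome 9, 21616169 to 21704230), changed by -2.55 ± 0.18 and kept 17.1%. Hltf changed by -2.37 ± 0.28 and Rad54l2 by -1.86 ± 0.12. Chd7 changed by -1.37 ± 0.21, Chd4 by -1.19 ± 0.14 and Ino80 by -1.03 ± 0.15. The weakest changes were those of Ep400 (-0.70 ± 0.12, 61.5% of control), Chd5 (-0.67 ± 0.22), Ercc6 (-0.59 ± 0.18) and Chd2 (-0.40 ± 0.11, 75.8%). In 5 libraries the targeted RNA lay within the range of the controls before the batch term: Chd2 replicate 2 at -0.06, Chd5 replicate 1 at -0.20, Srcap replicate 2 at -0.55, and 2 libraries that also showed another target lowered. The library labelled Ttf2 replicate 1 held Ttf2 at 0.06 and Smarcad1 at -1.98, while Smarcad1 reached no lower than -0.44 in any control. The library labelled Hells replicate 1 held Hells at -0.29 and Ercc6l at -1.41, while the 2 controls of its batch held Hells at 1 and 0.71. The library labelled Ercc6l replicate 1 held Hells at -2.57 beside Ercc6l at -2.37. Directions given for Ttf2, Hells and Ercc6l rest on these libraries as labelled.

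**Figure D2:**
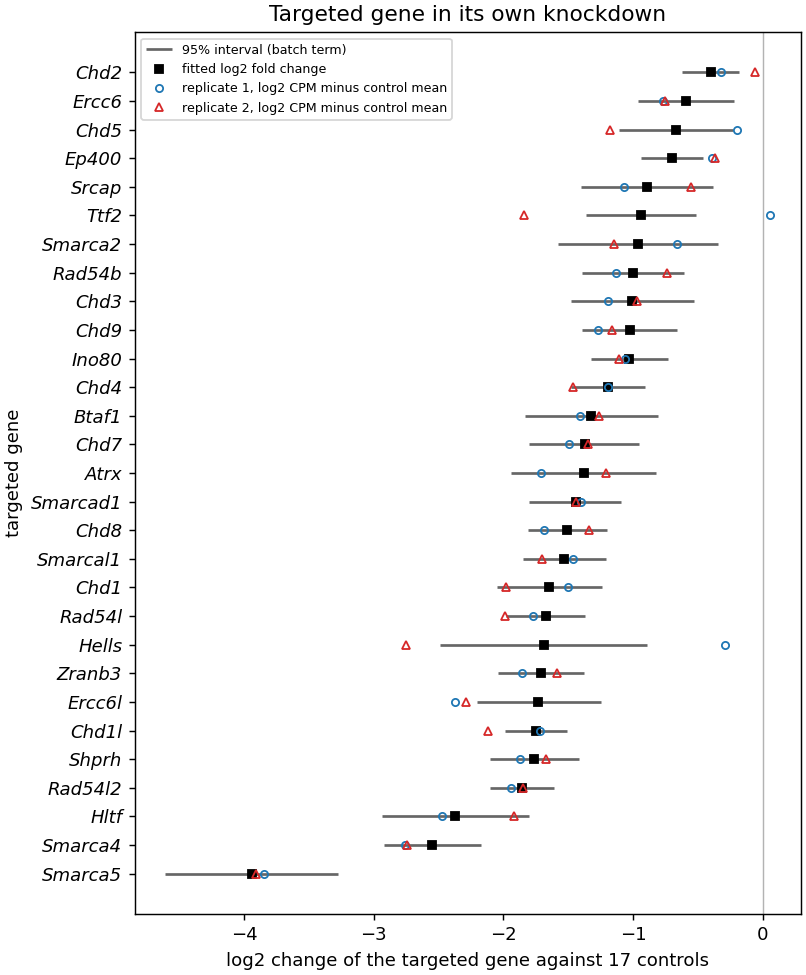
Log2 change of each targeted RNA against 17 controls (horizontal axis) for the 29 knockdowns (vertical axis), with the fitted value and its 95% interval and the deviation of each of the 2 replicates from the control mean. Every fitted value is below 0, from -0.40 for Chd2 to -3.94 for Smarca5, and the library labelled Ttf2 replicate 1 lies at 0.06.

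The second comparison asked how many genes changed with each knockdown. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4673 genes for Chd7, 4447 for Chd4, 2711 for Ep400, 1895 for Smarca4, 471 for Ino80, 469 for Smarca5, 321 for Hltf, 68 for Srcap, 43 for Chd8, 8 for Smarcad1 and 6 for Shprh. In Chd1, Chd1l, Chd9, Ercc6l, Rad54l, Rad54l2, Smarcal1 and Zranb3 only the target passed. No gene passed in Atrx, Btaf1, Chd2, Chd3, Chd5, Ercc6, Hells, Rad54b, Smarca2 and Ttf2. The counts at an unadjusted p under 0.05 in these 10 were 273, 1361, 798, 259, 1539, 291, 420, 1057, 691 and 4071, and DESeq2 called 3, 3, 0, 0, 3, 0, 2, 1, 1 and 685. In simulated counts with known changes the test recovered 31% of 2-fold and 82% of 4-fold changes for the Ttf2 design, and 58% and 95% for the Chd4 design. Among 60 pairs of controls set against the other controls, 7 pairs gave any call. The median was 0 by edgeR and the highest was 512, for controls 2 and 13, both of batch 10. These 2 held the mitochondrial RNA mt-Nd6 at 11.1 and 12.9 CPM. Chd1 replicate 1 (11.3) and Srcap replicate 1 (11.2), of the same batch, were as low. The other libraries of batch 10 held 78.1 to 107 CPM, and no other batch went below 35. The batch term does not describe this difference, and its bearing on the calls was not tested.

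**Figure D3:**
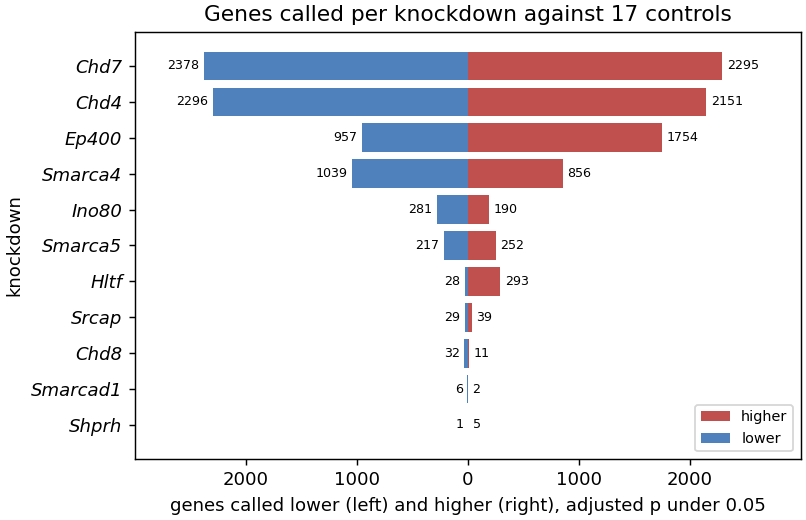
Genes called lower (left) and higher (right) against 17 controls at an adjusted p under 0.05 (horizontal axis) by knockdown (vertical axis). Knockdowns in which no gene other than the target was called are not drawn. Chd7, Chd4, Ep400 and Smarca4 have the longest bars.

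Knockdown of Chd4, the ATPase of the NuRD deacetylase complex (ENSMUSG00000063870.12, chromosome 6, 125095981 to 125130591), raised 2151 genes and lowered 2296. The balance turned with a GC trend as an offset (2994 higher and 1910 lower), the corrected counts (3464 and 2790), DESeq2 (2504 and 1847), no batch term (2073 and 1614), no filter (2085 and 2005), and Chd4 and the controls alone (1246 and 739). The balance turned with the replicate number as a block as well (1082 and 1017). It also turned without replicate 1 (1395 and 1380), and 1612 of the rises and 685 of the falls were at least 2-fold. Its 2 paralogs rose, Chd3 by 2.29 ± 0.21 (79.7 and 62.7 CPM against 17.4 ± 7.08) and Chd5 by 2.21 ± 0.20. Other strong rises, among genes with an average log2 CPM of at least 3, were in Ppp2r2c, a regulatory subunit of protein phosphatase 2A (2.74 ± 0.17, chromosome 5, 36868513 to 36955078), the collagen genes Col7a1 (2.68 ± 0.22) and Col2a1 (2.44 ± 0.28), the collagen chaperone Serpinh1 (2.20 ± 0.24), the neuronal kinesin Kif1a (2.31 ± 0.50), Ddit4, Cacna1b and Kalrn. Strong falls at that level were in Cbr3 (-3.49 ± 0.33), the activin subunit Inhbb (-3.21 ± 0.43), the cholesterol exporter Abca1 (-2.91 ± 0.22, 12 and 12.7 CPM against 78.7 ± 15.0), Fgf17 (-2.63 ± 0.34), Zfp827, Pdzd2 and the homeobox gene Gbx2. Rbfaos also fell, by 2.73 on the log2 scale, but it is annotated by name as antisense to another gene and how strand was used in counting is not given, so its value is uncertain.

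Members of several gene lists fixed in advance were called with Chd4. Of 32 DNA replication genes 16 fell and none rose over all genes tested, and 21 fell adjusted over the list alone. Their median was -0.42, with Rfc5 at -0.64 ± 0.10, Pole at -0.54 ± 0.11 and Rrm1 at -0.70 ± 0.14 (adjusted p = 0.587 with an estimated correlation). Of 21 homologous recombination genes 8 fell, 12 adjusted over the list alone, among them Bard1 (-0.78 ± 0.14), Fancd2 (-0.78 ± 0.16) and Brca1 (-0.69 ± 0.14), with adjusted p = 0.635 with an estimated correlation. Of 15 trophectoderm markers 7 rose, 8 adjusted over the list alone, with a median of 0.99 (adjusted p = 0.625 with an estimated correlation). They included the placental homeobox gene Esx1 (2.64 ± 0.33, 3.81 and 3.95 CPM against 0.803 ± 0.303), Krt19 (2.59 ± 0.35), Dlx3 (2.21 ± 0.42) and Tfap2c (1.41 ± 0.27). Of 22 p53 targets 11 rose and 1 fell, 12 and 1 adjusted over the list alone. Btg2 rose by 1.14 ± 0.19 and Plk2 by 1.34 ± 0.24, while Ddb2 changed by -1.21 ± 0.18 (adjusted p = 0.587 with an estimated correlation). The Nodal antagonists Lefty1 (1.34 ± 0.34) and Lefty2 (1.44 ± 0.30) were among the 3 of 7 Nodal and TGF-beta targets that rose, with 4 rising and 1 falling adjusted over the list alone and adjusted p = 0.769 with an estimated correlation. Both replicates lay on the same side of the control mean in 99.7% of the 4447 genes. The genes were called from these same 2 libraries, which favours such a share in advance, so it does not test replication. Without replicate 1 there were 2775 calls and without replicate 2 there were 2262, and RLE factors in place of TMM gave 2518 higher and 1615 lower.

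Knockdown of Ep400, the ATPase of the TIP60 complex that also deposits H2A.Z (ENSMUSG00000029505.17, chromosome 5, 110664373 to 110770717), raised 1754 genes and lowered 957, and 1202 of the rises and 99 of the falls were at least 2-fold. The list with the largest change was that of 2-cell-like genes, which mark a rare early-embryo-like state in these cultures. Of its 16 members 14 rose and 15 rose adjusted over the list alone, with a median of 3.91 (adjusted p = 0.505 with an estimated correlation). Usp17le rose by 3.94 ± 0.47, Usp17lc by 4.78 ± 0.69 and Arg2, an arginase, by 4.32 ± 0.57. Usp17le stood at 1.99 CPM in replicate 1 and 11 CPM in replicate 2 against 0.625 ± 0.337 in the controls. Over the list, replicate 1 had a median deviation of 1.72 from the control mean and replicate 2 of 4.25. Usp17l and Zscan4 genes are near-identical copies, so their separate values are uncertain. Other strong rises, among genes with an average log2 CPM of at least 3, were in Lrrn2 (2.33 ± 0.34), Megf11 (2.15 ± 0.26, 33.9 and 51.2 CPM against 11.7 ± 3.53), the cyclin-like gene Ccno (2.00 ± 0.34), Exoc3l, Soga3, Ier5l, Marveld1 and the imprinted cell cycle inhibitor Cdkn1c (1.73 ± 0.32). Rbfaos, an antisense gene, was at 2.82 ± 0.36. Rmrp, the RNA of RNase MRP, was called at 1.83 ± 0.52, yet its 7170 and 5330 CPM lay within the spread of the controls (6030 ± 4430), so that call rests on the batch term.

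Some members of other lists also rose with Ep400. Of 17 primitive endoderm markers 9 rose, 13 adjusted over the list alone, with Sox17 at 3.28 ± 0.73, Gata6 at 2.38 ± 0.62 and Sparc at 0.79 ± 0.20 (adjusted p = 0.763 with an estimated correlation). Of 18 Hox genes 7 rose and 11 rose adjusted over the list alone, with Hoxa13 at 4.28 ± 0.79 and Hoxc12 at 2.57 ± 0.57 from 0.0614 and 0.149 CPM in the controls (adjusted p = 0.505 with an estimated correlation). Of 25 germline genes 11 rose and 1 fell, 14 and 1 adjusted over the list alone, and Dazl stood at 1.40 ± 0.31 and Mael at 1.39 ± 0.30 (adjusted p = 0.733 with an estimated correlation). The BMP targets Id4 (1.82 ± 0.30), Id3 (0.91 ± 0.26) and Id1 (1.25 ± 0.39) were among 5 of 9 that rose, 6 adjusted over the list alone (adjusted p = 0.587 with an estimated correlation). Evx1 (2.74 ± 0.37) was among 4 of 16 mesendoderm genes that rose, 5 adjusted over the list alone, and Pax2 (2.36 ± 0.47) among 3 of 14 neuroectoderm genes, 7 adjusted over the list alone (adjusted p = 0.769 with an estimated correlation for both). Jun (1.22 ± 0.34) and Myc (1.12 ± 0.34) were among 5 of 15 immediate early genes that rose, 6 adjusted over the list alone (adjusted p = 0.853 with an estimated correlation). Of 18 naive pluripotency genes 6 rose and none fell over all genes tested, 7 adjusted over the list alone, including Tbx3 (1.54 ± 0.29) and Prdm14 (1.15 ± 0.18), with adjusted p = 0.763 with an estimated correlation.

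Of 24 mitosis genes 9 fell with Ep400, 13 adjusted over the list alone, with Top2a at -0.80 ± 0.22 and Ccnb1 at -0.64 ± 0.18 (adjusted p = 0.587 with an estimated correlation). Of 32 DNA replication genes 8 fell, 17 adjusted over the list alone, with Rfc4 at -0.98 ± 0.26 and Mcm6 at -0.37 ± 0.10 (adjusted p = 0.505 with an estimated correlation). The glycolytic genes Ldha (-1.24 ± 0.18, 425 and 227 CPM against 704 ± 107), Tpi1 (-0.97 ± 0.17) and Pdk1 (-0.64 ± 0.14) fell, within a list of 24 in which 4 fell and the hypoxia gene Ndrg1 rose. Adjusted over the list alone 5 fell and 1 rose, with adjusted p = 0.763 with an estimated correlation. The NuRD subunits Rbbp7 (-0.78 ± 0.16), Rbbp4 (-0.76 ± 0.17) and Hdac1 (-0.53 ± 0.17) were the 3 of 12 that fell, also adjusted over the list alone (adjusted p = 0.587 with an estimated correlation, replicate medians 0.11 and -0.33). Among genes with an average log2 CPM of at least 3, strong falls were in the PCNA-binding factor Pclaf (-1.64 ± 0.32), Sfmbt2 (-1.5 ± 0.29), the X-linked noncoding RNA Firre (-1.41 ± 0.26), Zfp280c, Prps1, Rps6ka6, the histone acetyltransferase Hat1, Acsl5 and Iqgap2. The count rests on replicate 2: without it 2 genes were called, and without replicate 1 there were 2169. Both replicates lay on the same side of the control mean in 95.1% of the 2711 genes, which were called from these same 2 libraries.

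Knockdown of Smarca4 raised 856 genes and lowered 1039. The balance turned with a GC trend as an offset (1603 higher and 1105 lower), with the corrected counts (1755 and 1244) and with Smarca4 and the controls alone (831 and 605). Among genes with an average log2 CPM of at least 3, strong falls were in the membrane protein gene Emp1 (-4.45 ± 0.38, chromosome 6, 135362545 to 135383173), at 0.213 and 0.702 CPM against 9.22 ± 3.30, thyrotropin-releasing hormone Trh (-3.09 ± 0.30), cyclin D2 gene Ccnd2 (-2.88 ± 0.28), Myrf (-2.63 ± 0.24), Acss1, Tnfrsf1b, the receptor kinase Kit (-2.23 ± 0.27), Ly6g6e, Laptm5 and Pck2. Strong rises at that level were in Pdzd2 (2.50 ± 0.23, 175 and 262 CPM against 45.4 ± 10.8), Ccno (2.43 ± 0.32), beta-spectrin Sptb (1.72 ± 0.17), Megf11 (1.68 ± 0.27), Sema3e (1.60 ± 0.20), Tppp3, Igdcc3, Marveld1, Zc3h12a and Lrrn4. Of 22 genes of the integrated stress response, which supplies amino acids under stress through ATF4, 12 fell and none rose over all genes tested. Adjusted over the list alone 16 fell, and the median was -1.15 (adjusted p = 0.749 with an estimated correlation). Asparagine synthetase Asns changed by -1.28 ± 0.27, Psat1 of serine synthesis by -1.48 ± 0.35, Mthfd2 by -1.26 ± 0.28 and Cth by -1.16 ± 0.23. Of 24 interferon response genes 8 fell and 1 rose, 10 and 1 adjusted over the list alone (adjusted p = 0.587 with an estimated correlation). Xaf1 changed by -3.41 ± 0.44, the RNA sensor Ddx58 by -1.04 ± 0.20 and Oas1a by -1.23 ± 0.25.

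Of 24 glycolysis and hypoxia genes 7 fell and 1 rose with Smarca4, 9 and 1 adjusted over the list alone, with Pfkp at -1.38 ± 0.23, Vegfa at -1.76 ± 0.33 and Ldha at -0.69 ± 0.17 (adjusted p = 0.769 with an estimated correlation). The cholesterol synthesis genes Sqle (-0.50 ± 0.11) and Nsdhl (-0.83 ± 0.19) were among the 4 of 23 that fell, also adjusted over the list alone (adjusted p = 0.865 with an estimated correlation). The 4 of 18 Hox genes that rose were neighbours in 1 cluster on chromosome 2, Hoxd9 (3.43 ± 1.02), Hoxd10 (3.84 ± 1.03), Hoxd11 (3.25 ± 0.72) and Hoxd12 (3.48 ± 0.82), from at most 0.066 CPM in the controls, and 6 rose adjusted over the list alone (adjusted p = 0.505 with an estimated correlation). Usp17le (2.33 ± 0.46) and Zscan4e (2.29 ± 0.63) were the 2 of 16 2-cell-like genes that rose, against 9 adjusted over the list alone (adjusted p = 0.83 with an estimated correlation). Without replicate 1 there were 617 calls in the Smarca4 knockdown (313 higher and 304 lower) and without replicate 2 there were 643. Its replicate 1 lay in batch 2, with an antisense log2 ratio of -8.78, and its replicate 2 in batch 1, with -9.48.

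Knockdown of Smarca5 raised 252 genes and lowered 217, against 43 and 70 with Smarca5 and the controls alone in the fit. Of 17 primitive endoderm markers 6 rose, 12 adjusted over the list alone, with a median of 1.57 (adjusted p = 0.587 with an estimated correlation). Replicate 1 had a median deviation of 0.45 from the control mean and replicate 2 of 2.29. The basement membrane collagens Col4a1 (1.84 ± 0.37, 22.9 and 60.4 CPM against 12.5 ± 5.81) and Col4a2 (1.99 ± 0.40), the endoderm factor Gata4 (1.67 ± 0.34) and the receptor Pdgfra (1.96 ± 0.51) rose. Krt19 was the 1 of 15 trophectoderm markers that rose (1.95 ± 0.35), and Col5a2 (1.74 ± 0.32) and Vim (0.79 ± 0.21) were the 2 of 16 fibroblast and matrix genes, whose replicate medians were 0.27 and -0.09. Those lists gave 3 and 2 rises adjusted over the list alone, and adjusted p = 0.587 and adjusted p = 0.749 with an estimated correlation. Capn2 rose by 1.60 ± 0.23. Atxn1l, a transcriptional corepressor gene, fell by 1.98 on the log2 scale (11.3 and 8.58 CPM against 44.4 ± 8.89), and Tcfl5 by 1.52. Without replicate 1 there were 223 calls and without replicate 2 there were 175.

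Knockdown of Ino80 (ENSMUSG00000034154.15, chromosome 2, 119373042 to 119477687) raised 190 genes and lowered 281, against 247 and 207 without a batch term and 1811 and 1636 with the corrected counts. Lefty1 (1.89 ± 0.35, 121 and 204 CPM against 82.8 ± 35.2) was among the 2 of 7 Nodal and TGF-beta targets that rose, against 3 adjusted over the list alone (adjusted p = 0.749 with an estimated correlation). The Notch ligand Dll1 (1.72 ± 0.47), Ccno (1.53 ± 0.40), Mrc2, Bcl11a, Rac3, Mycl (1.12 ± 0.23), Acadvl, Zfp689 and B4galt2 also rose. Among genes with an average log2 CPM of at least 3, strong falls were in Rnf17, a germline gene (-2.18 ± 0.35), the mitochondrial genes Fundc2 (-1.88 ± 0.27) and Suclg2 (-1.40 ± 0.17, 9.44 and 7.19 CPM against 19.9 ± 2.91), Zfand1, Abcb1a, Capza1, Pclaf, the translesion polymerase Poli (-1.36 ± 0.21) and Vps41 (-1.35 ± 0.19). Zfp988 (-2.19 ± 0.62) belongs to a cluster of near-identical zinc finger genes and is uncertain. Among 87 cytosolic ribosomal protein genes and copies the median was -0.32, and Rpl7l1 (-0.68 ± 0.12) and Rpl17 (-1.03 ± 0.28) fell, also adjusted over the list alone (adjusted p = 0.915 with an estimated correlation). The count fell to 2 without replicate 2 and was 945 without replicate 1 (476 higher and 469 lower). Without control 10, the only control of its batch, it was 134, and with the knockdown and the controls alone in the fit it was 12. Ino80 replicate 1 lay in batch 9, which held no control, so leaving out replicate 2 left no control of the same batch.

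Fewer genes changed in Srcap, Chd8, Smarcad1 and Shprh. With Srcap, which exchanges H2A.Z into nucleosomes, 39 genes rose and 29 fell (59 and 84 with the antisense share as a covariate, 142 and 146 with a GC trend), including the tau gene Mapt (1.40 ± 0.33), Ddah1 (1.24 ± 0.20), Clip3 (-1.16 ± 0.25) and Ubash3a (-0.96 ± 0.19). No gene was called without either of its replicates, where 1 library was taken to vary like the other groups. The count ranged from 17 without control 4 to 135 without control 13, and was 36, 105 and 44 without controls 2, 3 and 17. Without the 3 libraries of doubtful label (Ttf2, Hells and Ercc6l replicate 1) it was 7. The 2-cell-like and primitive endoderm lists had medians of 1.57 and 0.97 with Srcap, with 0 members called over all genes, 6 and 8 adjusted over the list alone, and adjusted p = 0.587 with an estimated correlation for both. With Chd8, 11 genes rose and 32 fell (248 and 194 with the corrected counts, 100 and 58 with no filter), including the RNA helicase gene Dhx34 (1.41 ± 0.27), Psrc1 (0.82 ± 0.18), the deubiquitinase Usp11 (-1.53 ± 0.16, 7.54 and 10.5 CPM against 24.3 ± 5.38) and Tex14 (-1.28 ± 0.27). Psrc1 was the 1 of 22 p53 targets that rose with Chd8, 6 adjusted over the list alone, and their median was 0.34 (adjusted p = 0.505 with an estimated correlation). Leaving out replicate 1 or replicate 2 of Chd8 left 5 and 11 calls, of which 0 and 7 were rises. With Smarcad1, Miip rose (0.88 ± 0.18), and Ifitm3 (-1.22 ± 0.23) was among 6 falls, against 2 rises (27 and 59 with the corrected counts, 32 and 44 with no filter). Without replicate 1 there was 1 call and without replicate 2 there were 0 by edgeR, against 1363 genes at an unadjusted p under 0.05 and 33 by DESeq2 with both. In Shprh the 5 rises were in Scand1, Zfp335os, Scarna2, Snord55 and Pdzrn3, named here after their values were seen. Zfp335os is an antisense gene and is uncertain. Of its 6 calls, target included, 3 had both replicates on the same side of the control mean. There was 1 call without replicate 2 and 212 without replicate 1.

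With Chd7, 28 of 66 replication-dependent histone genes rose, 37 adjusted over the list alone, led by Hist1h2ac (2.48 ± 0.58) and Hist1h2ag (2.41 ± 0.54), with adjusted p = 0.772 with an estimated correlation. These genes are near-identical copies and are uncertain. Of 17 primitive endoderm markers 7 rose with Chd7, 10 adjusted over the list alone, with Col4a1 at 1.42 ± 0.36 (adjusted p = 0.763 with an estimated correlation). Egr1 (1.24 ± 0.30) and Junb (1.08 ± 0.32) were among 5 of 15 immediate early genes that rose, 7 adjusted over the list alone (adjusted p = 0.819 with an estimated correlation). Arhgap5 (-1.5 ± 0.42), Kbtbd8 (-1.39 ± 0.33), Haus3, Trim59 and the noncoding RNA Snhg14 fell. Zfp979, Zfp990 and 3 other genes of a cluster of near-identical zinc finger genes on chromosome 4 also fell, and their values are uncertain. Without Chd7 replicate 1 there were 0 calls by edgeR, and without replicate 2 there were 5135. Both Chd7 replicates lay on the same side of the control mean in 97.7% of the 4673 genes, which were called from these same 2 libraries. The share was 100% for Hltf, so it cannot tell an effect of the target from library quality. The median deviations of Chd7 replicates 1 and 2 were 1.06 and 0.88 for the histone list and 1.02 and 0.95 for primitive endoderm. With Hltf, 293 genes rose and 28 fell, including Sac3d1 (1.5 ± 0.37) and the retinoblastoma relative Rbl1 (-0.87 ± 0.19). Zfp600 (-1.06 ± 0.29) lies in the same zinc finger cluster and is uncertain. Hmga1b was called at 1.62 ± 0.41, yet its 317 and 344 CPM lay within the spread of the controls (219 ± 143), and without batches 1, 2 and 4 it was at -0.2. The p53 targets Bax (0.76 ± 0.18), Phlda3 (0.98 ± 0.25), Psrc1 (0.65 ± 0.16) and Bbc3 (1.06 ± 0.29) were the 4 of 22 that rose with Hltf, while 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.749 with an estimated correlation). Without Hltf replicate 2 there were 0 calls and without replicate 1 there were 2580. Without controls 1, 7, 8, 14, 15, 16 and 17 the count for Hltf was 4, 710, 184, 488, 105, 129 and 198, and without the libraries labelled Ttf2, Hells and Ercc6l replicate 1 it was 201. Hltf replicate 1 lay in batch 6, which held no control, so leaving out Hltf replicate 2 left no control of the same batch. Chd7 replicate 1 and Hltf replicate 2 both lay in batch 2. There their antisense log2 ratios of -9.71 and -9.57 were low beside the -8.66 and -8.72 of its 2 controls. With that ratio as a covariate 1 gene was called for each, its own target, and without batches 1, 2 and 4 there were 0 by edgeR for both. With all libraries and no covariate, the counts at an unadjusted p under 0.05 were 7970 and 4890, and DESeq2 called 5074 and 1261.

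Across the 29 knockdowns, 212 of 1044 combinations of list and knockdown were called by camera with a preset correlation, 0 with an estimated correlation, and 32 by fry, which tests whether a list's genes move 1 way. Of the 212 calls, 29 were called in the same direction by fry. List calls also lay in knockdowns in which no gene was called. Btaf1 had 11 upward and 3 downward and Ttf2 had 11 and 1, against 3 and 2 for Chd4 and 9 and 8 for Ep400. The knockdowns share controls, and how often a list would be called in 1 direction with no change was not computed. The lists called upwards most often were p53 targets in 11 knockdowns, immediate early genes in 10, primitive endoderm in 9, and formative and primed pluripotency and Wnt targets in 8 each. Trophectoderm, neuroectoderm, FGF and ERK feedback and Nodal and TGF-beta targets were called up in 7 each, Hox and mesendoderm in 6 each, and germline, imprinted, fibroblast and matrix genes in 5 each. BMP targets went up in 5 and down in 1, 2-cell-like genes up in 9 and down in 5, and replication-dependent histones up in 7 and down in 5. Downward calls were most frequent for cytosolic ribosomal proteins, in 11 against 1 upward, and for the integrated stress response and naive pluripotency, in 8 each against 0 and 1 upward. Glycolysis and hypoxia genes went down in 7 and up in 1, homologous recombination down in 7, mitosis in 4, DNA replication, lysosome and mitochondrially encoded genes in 3 each, interferon response in 2, and ribosome biogenesis, the unfolded protein response and NuRD subunits in 1 each. Cholesterol synthesis went up in 2 and down in 3, the nuclear respiratory chain up in 3 and down in 4, and SWI/SNF subunits up in 3 and down in 1. Subunits of INO80, SRCAP and TIP60 went up in 1, and core pluripotency and heat shock genes were called in none by camera.

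**Figure D4:**
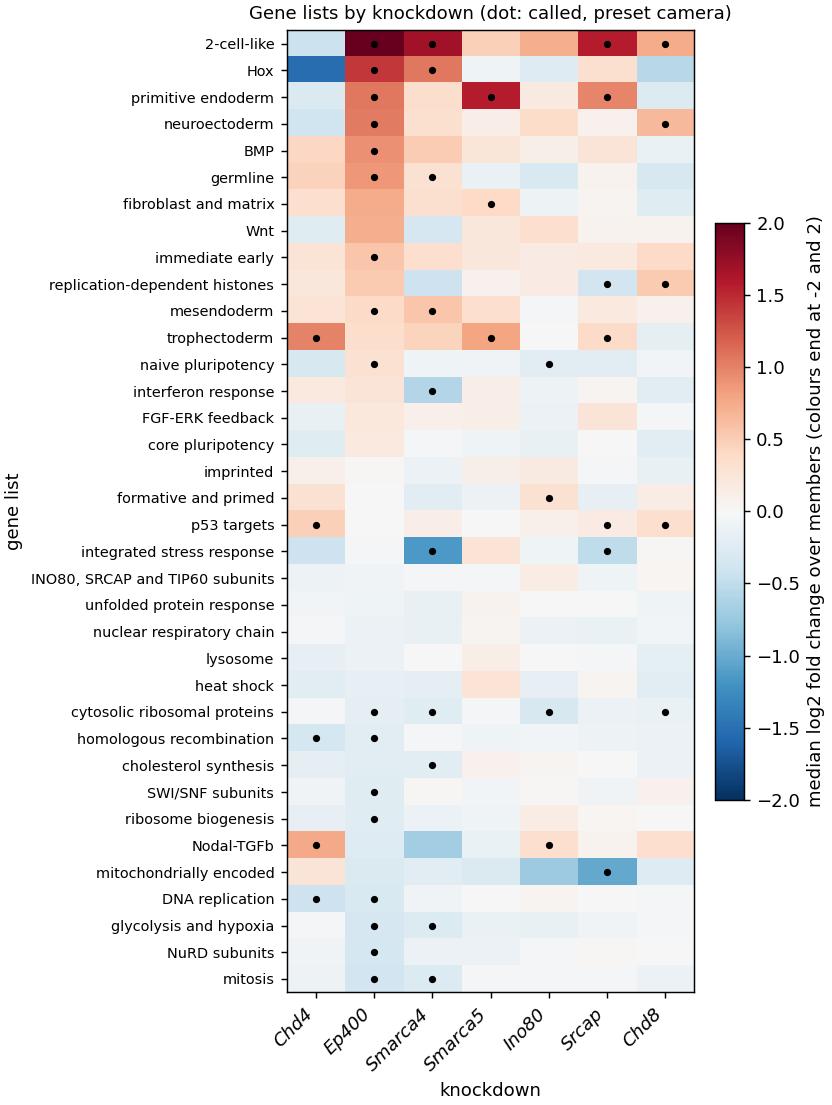
Median log2 fold change over the members of each fixed gene list (vertical axis) in 7 knockdowns, Chd4, Ep400, Smarca4, Smarca5, Ino80, Srcap and Chd8 (horizontal axis), with a dot where camera with a preset correlation called the list. Colours end at -2 and 2, and the median of 3.91 for 2-cell-like genes in Ep400 lies beyond them, while that of Hox genes in Chd4 rests on genes at or near no counts.

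A further comparison asked whether depletion of 1 remodeler went with a change in the RNA of another. Of 812 such tests 36 were called, 9 higher and 27 lower, in 5 knockdowns, and 4 of the 36 were within a family. Fewer were called without a batch term, and most ended with the replicate number as a block, while more were called with the corrected counts. The largest were the rises of Chd3 and Chd5 with Chd4. Smarca2, the other SWI/SNF ATPase, rose by 1.93 ± 0.25 with Ep400 and by 1.17 ± 0.27 with Smarca5. Chd3 changed by -1.20 ± 0.24 with Smarca5. Chd2 changed by -0.66 ± 0.11 with Chd4, which also lowered Shprh (-0.60 ± 0.15) and Rad54l (-0.52 ± 0.14). Ep400 knockdown lowered Chd7 (-0.84 ± 0.21) and Chd9 (-0.58 ± 0.14). Of its relatives Ino80 rose by 0.37 ± 0.12 and Srcap by 0.62 ± 0.21. The other calls comprised 13 in Chd7, where no gene was called by edgeR without replicate 1. When Ep400 replicate 2 was left out, 2 genes in all were called. Deviations from the control mean in Ep400 replicates 1 and 2 were 1.49 and 2.2 for Smarca2, -0.74 and -0.86 for Chd9 and 1.37 and 1.07 for Srcap, but -0.19 and -1.23 for Chd7 and -0.05 and 0.58 for Ino80.

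Relatives were also contrasted directly, since a gene called in 1 knockdown and not in another is not thereby shown to differ. Over 22 pairs within 9 families, 2015 genes differed between Chd4 and Chd5 (1016 higher and 999 lower in Chd4), 1606 between Chd3 and Chd4, 1473 between Ep400 and Ino80 (865 higher and 608 lower in Ep400), 458 between Ep400 and Srcap, 357 between Smarca2 and Smarca4, and 205 between Ino80 and Srcap. Chd7 and Chd8 differed in 22 genes, and the remaining pairs in at most 4.

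Genome-wide profiles of relatives were compared over all genes tested. The mean Pearson correlation of log2 fold changes was 0.211 over the 22 within-family pairs and 0.153 over the other 384, a difference of 0.058 (two-sided permutation of the family labels over 29 knockdowns, p = 0.0299). The highest within-family values were 0.57 for Chd7 and Chd9, 0.48 for Hltf and Ttf2, 0.45 for Ercc6 and Ercc6l and 0.34 for Chd7 and Chd8. Some pairs outside families were as high, such as 0.53 for Chd7 and Ttf2 and 0.49 for Chd1l and Chd9. Both Ercc6 libraries and Ercc6l replicate 2 lay in batch 8, which held no control. Atrx and Srcap, each with a library in that batch, correlated with Ercc6 at 0.46 and 0.44. With the antisense share as a covariate, which ended all calls of Chd7 and Hltf but their targets, the difference was 0.05 (permutation p = 0.0157). The difference without these 2 knockdowns was not computed. Comparisons share their controls, and simulated unchanged knockdowns gave 0.115 and 0.112, a difference of 0.003. The covariances were 0.127 and 0.0787, against 0.0467 and 0.0428 in the simulation. The simulation drew each gene independently, so it holds no shift of a whole library beyond the batch term and may give too low a reference. Splitting the controls set the 2 knockdowns of a pair against different ones, but the batch terms were still fitted from all libraries. The difference was then 0.061 (permutation p = 0.0174). Among pairs with no batch in common it was 0.072 (p = 0.00988), and without a batch term it was 0.109 (p = 0.0818), no longer past the threshold. Nor did it pass with no filter on low counts (0.025, p = 0.229), with the corrected counts (0.083, p = 0.0586) or with a GC trend as an offset (0.052, p = 0.0573). With the replicate number as a block it was 0.023 (p = 0.393). Across genes, which are not independent replicates, Chd7 and Hltf correlated at 0.68 (0.62 with split controls and 0.19 simulated). Their covariance was 0.607 against 0.0582 in the simulation, and they shared 252 rises where independent lists would share 31.3, with 1 library of each in batch 2. Chd4 and Ep400 correlated at 0.17 (0.13 with split controls and 0.05 simulated), with a covariance of 0.140 against 0.0187. They shared 404 rises against 175 for independent lists and 245 falls against 102, while 235 genes were called in opposite directions. Counts for independent lists do not allow for the shared controls. Ep400 and Smarca4 correlated at 0.09 (0.05 with split controls and 0.04 simulated), with a covariance of 0.0629 against 0.0123. Chd4 and Smarca4 correlated at -0.01 (-0.05 with split controls and 0.04 simulated), and 367 of their shared calls were in opposite directions, against 141 shared rises and 166 shared falls.

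**Figure D5:**
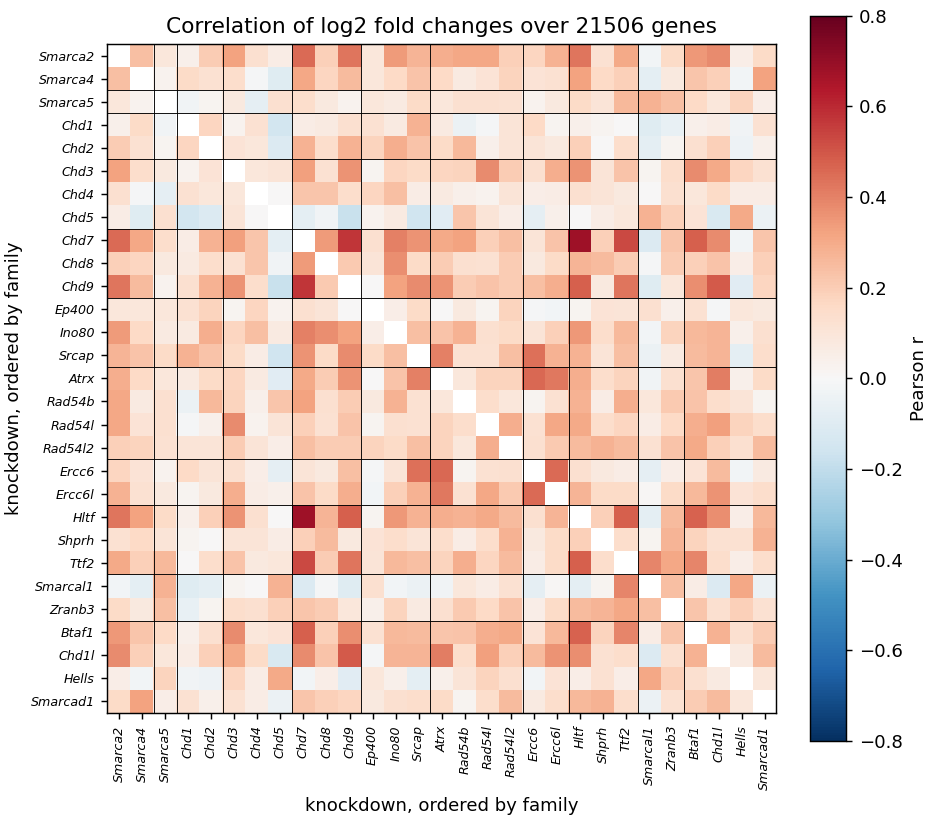
Pearson correlation of log2 fold changes over 21506 genes between each pair of the 29 knockdowns (both axes, ordered by family). Chd7 and Hltf correlate at 0.68, Hltf and the libraries labelled Ttf2 at 0.48, and Chd4 and Chd5 at 0.00.

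50 genes were called in 1 direction in at least 4 knockdowns, 32 up and 18 down. This count was 6 with the antisense share as a covariate, 8 with a GC trend as an offset, 15 without a batch term, 853 with no filter on low counts and 1318 with the corrected counts. With the replicate number as a block it was 0 by edgeR. The knockdowns share controls, and how many genes would recur with no change was not computed. 3 genes were called in 5 knockdowns: the PWWP domain gene Pwwp2b, the collagen gene Col27a1 and Tmc8. Chd7 and Hltf were among the 5 for each, so that 3 knockdowns were left without them, and Pwwp2b fell with Smarca4. Cdk6, a G1 cyclin-dependent kinase gene, fell with Chd4, Chd7, Ep400 and Smarca4, and Slfn9 with Ep400, Hltf, Smarca4 and Smarca5. The collagen genes Col2a1 and Col16a1 rose with Chd4, Chd7, Ep400 and Smarca4. Nova2 and Rundc3a also rose in 4, and Crybg3 fell in 4 and rose with Smarca4, with Chd7 and Hltf among the 4 for these 3 genes. Without Chd7 and Hltf only Mpzl2 and Msln of the 50 were called in 1 direction in 4 knockdowns, and Msln fell with Chd4. Both are named here after their values were seen.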

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

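Tests chosen only after the result was seen were those of a swap, of a mixture and of a fall of Hells with Ercc6l for the library labels, that of the antisense share as a covariate for Chd7, and those of shuffled coding partners and of the coding level alone for antisense genes.

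The corrected counts, used only as an alternative, held values far above the raw count of the same gene and library: 18 values exceeded 1e+07 and were over 100 times the count. They belong to genes with at most 7 raw counts in that library. The highest were 4.2e+11 and 2.61e+11 for Gm11950 in Ep400 replicates 2 and 1, 9.56e+09 for Gm26619 in Chd8 replicate 1, 9.46e+09 for Rp31-ps19 in Rad54l replicate 1 and 7.6e+09 for Gm12834 in Rad54b replicate 2. Cpb2 reached 5.45e+08 and 4.51e+08 in Chd2 replicates 1 and 2, and Gm9523 4.77e+08 in Ino80 replicate 1. Gm36864 stood at 79200000 and 67600000 in Chd8 replicates 1 and 2, Gm11950 at 73400000 and 44700000 in Chd4 replicates 2 and 1, Gm49277 at 30900000 and 30400000 in Chd2 replicates 2 and 1 and at 15400000 in Ep400 replicate 1, and Gm11950 at 23600000 and 18600000 in controls 4 and 9. Gm48068 stood at 11200000 in Chd9 replicate 1. The value of Gm11950 rounds to the whole column total in both Ep400 libraries. That alternative kept only genes that passed the filter on the raw counts, with library totals taken over those genes. The raw counts of these values lie under the minimum count of 10 of that filter, and whether any of these genes passed was not checked. Counts from the corrected counts are taken as uncertain. The cause of these values was not tested.

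In the library labelled Ttf2 replicate 1, Ttf2 RNA was at the control level and Smarcad1 RNA was lowered. A swap with a Smarcad1 library is excluded, since the higher of the Smarcad1 values in those libraries was -1.4, below the lowest control at -0.44. A wrong label or wrong esiRNA for this library alone stays open: over 7 other genes called with Smarcad1 its mean deviation was 0.93 against a median of 0.14, above 100% of the libraries not labelled Smarcad1. In the library labelled Ercc6l replicate 1, a mixture of separate knockdown cells is excluded because Hells and Ercc6l kept only 16.8% and 19.3% of the control level. A fall of Hells with Ercc6l stays open: Hells stood at -0.44 in Ercc6l replicate 2, within controls that reached -1.22. In the library labelled Hells replicate 1, Ercc6l was at -1.41 and Hells at -0.29. That is within the range of all controls but below the 1 and 0.71 of the 2 controls of its batch. Ercc6l replicate 2 is 1 library, and the label of the other is in doubt. No other biological explanation was tested for these libraries.

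Among the control libraries alone, those of batches 1 and 2 were compared with those of the other batches. Antisense genes were higher by a median of 2.26 over 903 genes, while protein-coding genes changed by a median of -0.08. Some knockdown libraries of batches 1 and 2 did not show this rise. Antisense genes whose coding partner was under 1 CPM rose by 0.07 (69 genes), against 2.97 where the partner was at 10 CPM or more (663 genes). This went against the prediction set for genomic DNA. The 2 sets were not matched for the level of the antisense gene itself, so genomic DNA is not excluded. A GC trend is excluded, since with it removed the rise was 2.36. Reads of the coding gene on the opposite strand may be the source, as the rise grew with the ratio of the coding gene to the antisense gene (Spearman rho 0.776 across genes, which are not independent replicates). Both quantities contain the level of the antisense gene, and with the coding partners shuffled 1000 times rho had a median of 0.478 and reached at most 0.549. With the level of the coding gene alone it was 0.455. The design gives no biological group that separates these batches, so none was tested.

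For the 4673 genes called with Chd7, a quality of the libraries that the batch term does not describe may account for part of the count. With the antisense share as a covariate their median change in the called direction went from 0.748 to 0.341, the median standard error from 0.218 to 0.211, and 1 gene stayed called, so the calls ended because the changes shrank. Without replicate 1, 0 of the 4673 were called by edgeR, where 7970 genes had an unadjusted p under 0.05 with both and DESeq2 called 5074. Such a loss had been set in advance to count against an effect of Chd7 depletion in each replicate, but that bound was wrong. It rests on 1 library, and Ep400 and Ino80 each had 2 calls without replicate 2. An effect of Chd7 depletion on these genes stays open.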

How the results depend on the processing

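Tests with the antisense share as a covariate, a GC trend, without batches 1, 2 and 4, without the 3 libraries of doubtful label, without single controls, and of lists, remodelers, relatives, recurrence and similarity with the block were chosen only after the data were seen. Total counts given neither here nor in the report, apart from those inside a range given, lay within 1.5 times of the total reported, and each target value that could be fitted was below the controls, for 28 targets without batches 1, 2 and 4, 24 with the controls alone and 29 otherwise. For each change below the cause was not tested, except that a 2-fold minimum can only lower a count. Where a count of 0 is given it is by edgeR.

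Without a batch term Chd7 had 1 call, Ep400 4421, Hltf 3, Smarcad1 0 and Srcap 151. The deposited batch-corrected counts gave 442 for Chd8, 4442 for Ep400, 958 for Hltf, 3447 for Ino80, 246 for Shprh, 2999 for Smarca4, 1397 for Smarca5, 86 for Smarcad1 and 844 for Srcap. RLE factors gave 188 for Hltf and 3 for Smarcad1. With no filter on low counts there were 158 for Chd8, 1842 for Hltf, 1030 for Ino80, 178 for Shprh, 76 for Smarcad1 and 344 for Srcap, and with a mean CPM of at least 1 there were 77 for Chd8, 530 for Hltf, 709 for Ino80 and 114 for Srcap. DESeq2 called 142 for Chd8, 1261 for Hltf, 1114 for Ino80, 10 for Shprh, 707 for Smarca5, 33 for Smarcad1 and 261 for Srcap. With only the knockdown and the controls in the fit there were 1985 for Chd4, 2 for Chd8, 1543 for Ep400, 758 for Hltf, 12 for Ino80, 1 for Shprh, 113 for Smarca5, 3 for Smarcad1 and 0 for Srcap. At least 2-fold were 2297 for Chd4, 1302 for Chd7, 20 for Chd8, 1301 for Ep400, 99 for Hltf, 226 for Ino80, 928 for Smarca4, 284 for Smarca5, 5 for Smarcad1 and 34 for Srcap.

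With the antisense share as covariate there were 1 for Chd7, 81 for Chd8, 4533 for Ep400, 1 for Hltf and 143 for Srcap. With the GC trend, which moved the median of all genes in Chd4 from -0.0773 to 0.0636, there were 306 for Chd7, 121 for Chd8, 1 for Hltf, 717 for Ino80, 1 for Shprh and 288 for Srcap. Without batches 1, 2 and 4 there were 0 for Chd7, 20 for Chd8, 0 for Hltf, 1 for Shprh, 0 for Smarcad1 and 34 for Srcap, and Smarca4 could not be estimated. Without the 3 libraries of doubtful label there were 201 for Hltf and 7 for Srcap. Leaving out 1 replicate of the knockdown or, for knockdowns with at least 50 calls, 1 control gave 2262 to 4698 for Chd4, 0 to 5135 for Chd7, 5 to 11 for Chd8, 2 to 3028 for Ep400, 0 to 2580 for Hltf, 2 to 945 for Ino80, 1 to 212 for Shprh, 617 to 1948 for Smarca4, 175 to 500 for Smarca5, 0 to 1 for Smarcad1 and 0 to 135 for Srcap.

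The replicate numbers share only a number. With the number as a block beside the batch there were 2099 calls for Chd4, 1 for Chd7, 3 for Chd8, 59 for Ep400, 1 for Hltf, 0 for Ino80, 1 for Shprh, 435 for Smarca4, 18 for Smarca5, 0 for Smarcad1 and 0 for Srcap. Numbers above 2 occur only among controls, so the block fits 15 controls exactly. Differences between replicates correlated over 0.1 in 114 of 406 pairs of knockdowns, with a median of 0.012 and a range from -0.72 to 0.68, and in 8 knockdowns with control 1 minus control 2. With the block, remodeler genes called fell to 5, genes differing between relatives to 2866 and genes recurring in at least 4 knockdowns to 0, and similarity was 0.023 (permutation p = 0.393). Cytosolic ribosomal proteins in Chd2 turned direction with the block (adjusted p = 0.00309 by camera), and the targets Chd2 (-0.29), Chd5 (-0.68) and Srcap (-0.62) no longer passed.

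The knockdowns with under 5 calls had 8 together. They had 592 without a batch term, 7534 with the corrected counts, 2079 with no filter, 25 at a mean CPM of at least 1, 16 with the GC trend and 720 with DESeq2. Leaving out 1 replicate gave 7 to 28. Remodeler genes called were 23 without a batch term and 66 with the corrected counts. Genes differing between relatives were 21597 with the corrected counts and 9559 with the GC trend. The 50 recurrent genes became 15 without a batch term, 1318 with the corrected counts, 853 with no filter, 89 at a mean CPM of at least 1, 6 with the antisense share and 8 with the GC trend. Of 212 list calls, 0 held by camera with an estimated correlation and 29 were called in the same direction by fry, which called 32 of all 1044 tests. Similarity within families was 0.109 without a batch term (permutation p = 0.0818), 0.083 with the corrected counts (p = 0.0586), 0.025 with no filter (p = 0.229) and 0.052 with the GC trend (p = 0.0573).

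Of the targets, 18 passed over all genes. Chd2 was at -0.20 without a batch term, Btaf1 at -0.60, Chd5 at -0.53 and Ttf2 at -0.09 without batches 1, 2 and 4, and Chd3 at -0.55 and Smarca2 at -0.52 with the controls alone, none of which passed. With 1 replicate left out Srcap (-0.81), Chd5 (-0.48), Hells (-0.95), Smarca2 (-0.63) and Ttf2 (-0.11) did not pass. Directions turned for the integrated stress response in Chd2 (adjusted p = 0.00561 by camera) and histones in Ercc6 (5.45e-10) without a batch term, for formative and primed genes in Ercc6l without the libraries of doubtful label (0.0163), and without batches 1, 2 and 4 for Hist1h3h (-0.06) and Hist1h3c (-0.08) in Chd7 and Hmga1b (-0.2) in Hltf.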

Other observations

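The tests of genes grouped by symbol stem were chosen after the data were seen, while the relation of call counts to the level and depletion of the targets was predicted before it was computed. Stems are the shared letters at the start of gene symbols, and 385 stems in 5 knockdowns gave 1925 camera tests, of which 65 were called with a preset correlation and none with an estimated one. Counts of members called with Ep400 rest on its replicate 2, as stated for that knockdown above.

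Of 40 collagen genes 19 rose with Ep400, with a median log2 change of 1.02 (adjusted p = 1.68e-10, or 0.261 with an estimated correlation). Col15a1 stood at 2.96 ± 0.53, Col14a1 at 2.00 ± 0.33 and Col22a1 at 1.71 ± 0.26. With Chd4, 17 of the 40 rose, with a median of 0.96 (adjusted p = 8.25e-08, or 0.347 with an estimated correlation), among them Col6a1 (3.83 ± 0.58) and Col23a1 (2.63 ± 0.39). Voltage-gated calcium channel subunits moved with both: with Chd4 7 of 12 rose and 1 fell, led by Cacna1i (3.34 ± 0.38) and Cacna1e (3.12 ± 0.40), and with Ep400 7 rose, led by Cacna1s (3.57 ± 0.48). Adjusted p = 0.198 with an estimated correlation for both. Developmental transcription factors of the Pax and Pou families rose with Ep400, 4 of 6 and 6 of 14, with Pax7 at 3.55 ± 0.47, Pax8 at 2.04 ± 0.29 and medians of 2.20 and 0.85 (adjusted p = 0.198 with an estimated correlation for both).

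Intraflagellar transport genes, which build the primary cilium, mostly fell with Chd4: 8 of 15 fell and 1 rose, with Ift172 at -1.70 ± 0.15 and Ift52 at -1.05 ± 0.14 (adjusted p = 0.347 with an estimated correlation). Of 21 keratin genes 8 rose and 2 fell with Chd4, and 7 of 21 nucleoporin genes fell with Ep400, with a median of -0.33 (adjusted p = 0.347 with an estimated correlation for both). In Smarca4, 4 of 7 kallikrein genes fell with a median of -1.56 (adjusted p = 0.198 with an estimated correlation), and 4 of 8 Oas genes, which act in the response to double-stranded RNA, fell with a median of -1.06 (0.349). With Ep400 4 of the 8 Oas genes rose, with a median of 0.82 (adjusted p = 0.407 with an estimated correlation). The difference between these 2 knockdowns was not tested.

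The number of genes called per knockdown may follow how strongly the targeted gene is expressed. For this relation the number left out the target and was put on a log2 scale. Across the 29 knockdowns it correlated with the control log2 CPM of the target (Spearman rho 0.51, permutation p = 0.00542, adjusted p = 0.0108 over 2 relations; Pearson r 0.49, p = 0.0062, adjusted p = 0.0124), and r was 0.43 without Smarca2 and Chd4, which lie farthest from the median. No relation was detected with the log2 change of the target (rho -0.14, p = 0.456, and r -0.27, p = 0.149). That r was 0.01 without Smarca5 and Smarca4. Many knockdowns were tied at the lowest number, with no gene called besides the target. The numbers for Chd7 and Hltf were included, though only their targets stayed called with the antisense share as a covariate. Neither relation was computed without Chd7 and Hltf. The batches in which the knockdowns were made were not equal in number or controls, and most hold too few knockdowns for a value within a batch.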
